A study of Arabidopsis thaliana with 6 samples.

How the data were processed

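Roots of Arabidopsis seedlings were compared on 6 Agilent 2-colour arrays, 3 after low pH (pH 4.5, no Al) and 3 after Al (10 µM at pH 5.0), for 24 h. Per the labels, 10-day-old seedlings had been precultured at pH 5.5 without Al in 2% MGRL nutrient solution with 200 µM CaCl2, at 25 °C with 12 h of light per day, and 1 µg of total RNA was labelled. Each array held the STOP2-complemented line, in which STOP2 is expressed in the stop1-mutant background, against stop1-mutant. The STOP2-complemented line was in Cy5 on replicate 2 of each treatment and in Cy3 on the other 4 arrays. The 6 arrays were distinct biological replicates per the labels, and no pair of arrays held identical values.

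The authors scanned the arrays and extracted them with Agilent Feature Extraction 9.5.1.1. Per the file headers, the mean spot signals and the local background medians are intensity values of the green and red channel without correction or normalization. The deposited processed signals are intensity values that Feature Extraction had background-subtracted, spatially detrended and dye-normalized within each array by linear and lowess steps (smoothing 0.25). The deposited log ratio column is the log10 ratio of red to green processed signal and is not turned for dye orientation. The deposited series table holds log2 ratios of the STOP2-complemented line over stop1-mutant. For 37455 probes spotted once, 100% of its values equalled the turned ratio of the processed signals within 0.001, and its column medians lay between -0.07 and 0.05. Of 39102 spots per array, 37685 were not controls. Well above background were 59.4% to 77.0% of them in the green channel and 57.5% to 75.6% in the red channel. Saturated spots numbered 0, and 4 to 37 spots per array carried an outlier flag.

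Mean signals were background-corrected by normexp with an offset of 50 and loess-normalized within each array, with control and outlier spots given weight 0, in limma 3.58.1 (R 4.3.3, data.table version 1.17.8, jsonlite 2.0.0). Spots of a probe were averaged (23 of 37478 probes were spotted 10 times), and a gene with several probes was represented by the one with the highest mean intensity. Of 36907 genes or probes without a locus, 25384 were kept because they stood well above background in at least 1 of the 4 RNA classes (2 lines by 2 treatments) on all 3 arrays, 21335 of them with a locus identifier. The genome build of the probe coordinates is not given in the files. The reference annotation was used for symbols and neighbouring genes only.

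The log2 ratio of the STOP2-complemented line to stop1-mutant was fitted with lmFit for low pH, for Al and for a shared dye term, because the dye does not cancel in 2 arrays of one orientation and 1 of the other. Moderated tests of limma (eBayes, 3 residual and 2.80 prior degrees of freedom) gave p-values for low pH, Al, their difference and their mean, adjusted by Benjamini-Hochberg over the 25384 genes with a threshold of 0.05. The median SE of the log2 ratio was 0.095 for low pH and for Al, 0.13 for the difference and 0.069 over both. The precision rests on 3 arrays per treatment. On simulated data with 50 changed genes per fold size, this fit recovered 78%, 76%, 56% and 90% of genes changed 2-fold (low pH, Al, difference, both) and 88%, 84%, 80% and 92% of those changed 4-fold. It gave 13, 11, 6 and 15 calls among 25168 unchanged genes. The simulated noise was independent between genes and arrays, and many genes were changed at once, which the real arrays need not match. The recovered shares are therefore not the power of the real comparisons. A lone changed gene with the median SE needed 3.50-fold for low pH and for Al, 5.57-fold for the difference and 2.49-fold over both. With the tolerance list shifted in the simulated data, camera at the preset correlation also called 3 of the other lists at low pH, 0 in Al and 0 for the difference, lists that share genes with it included.

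Fixed before the data were examined were 22 gene lists: STOP1-regulated tolerance genes, other aluminium-resistance genes, GABA shunt and pH-regulating metabolism, potassium, proton and calcium transport, sulphate transport and sulphur starvation, nitrogen uptake and assimilation, iron-deficiency response, phosphate-starvation response, cell-wall loosening, phenylpropanoid and lignin synthesis and flavonoid synthesis. The others were oxidative-stress, heat-shock, pathogen-defence, hypoxia and abscisic-acid and dehydration responses, photosynthesis genes as markers of shoot tissue, and markers of root hairs, endodermis and suberin, xylem and phloem, root cap, and meristem and cell cycle. Of their 337 loci 322 were tested, and 13 are in more than 1 list. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 22 lists. Camera with an estimated correlation also rests on the 3 residual degrees of freedom, so a call lost there need not come from correlated members. Members were counted past the threshold over all genes and adjusted over the list alone.

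The rule for named genes, also fixed beforehand, took STOP2, STOP1 and every measured tolerance gene, and per treatment up to 10 called genes per direction with the same sign on all 3 arrays. For the difference it took up to 5 called genes per direction, and from every other list the called members or else the 2 with the smallest p. Values of 0 to 3 arrays above background per line decided whether a fold was a lower bound.

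Alternatives fixed beforehand were Feature Extraction processed signals, the series table, no background correction, an offset of 16, median centring, no or a strict dim-probe filter, no dye term, the replicate number as a block in place of the dye term, slide as a random block, the mean over a gene's probes, separate fits per treatment, trend and robust eBayes, leaving out each array, and a minimum of 2-fold. Added after seeing the data were the 4 arrays of slide 2 alone, with and without the dye term, and a comparison of Al with low pH within each line from single-channel intensities (limma lmscFit). Bootstrap intervals used 10000 draws at 95%. No sample was left out. No wild type was part of the series, so the size of the STOP2 effect relative to normal STOP1 function was not measured.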

Results

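RNA from roots of 10-day-old Arabidopsis thaliana seedlings was measured on 6 Agilent 2-colour arrays. Each array compared a STOP2-complemented line, which is the stop1-mutant carrying a STOP2 transgene, with the stop1-mutant itself. STOP1 is a zinc-finger transcription factor needed for root tolerance of acidity and aluminium (Al), and STOP2 is its closest homologue. In 3 arrays the roots had spent 24 h at pH 4.5 without Al (low pH), and in 3 they had spent 24 h at pH 5.0 with 10 µM Al (Al). Replicate 2 of each treatment carried the STOP2-complemented line in Cy5, and the other 4 arrays carried it in Cy3. Low pH replicate 1 lay on one slide, Al replicate 1 on another, and the remaining 4 arrays shared slide 2. No wild type was hybridised, so all values are of the STOP2-complemented line relative to stop1-mutant. Each array held 37685 non-control spots, of which 57.5% to 77.0% stood well above background per channel and none was saturated. The number of arrays, 3 per treatment, limits the precision. Per the labels, the series addresses what transcription STOP2 activates where STOP1 function is missing.

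At low pH, STOP2 itself (AT5G22890) was 26.0-fold higher in the STOP2-complemented line, and its array log2 ratios averaged 4.75 ± 0.36 (SD, n = 3). Among genes known or thought to act downstream of STOP1, CIPK23, a kinase that activates potassium and nitrate transporters, was 2.52-fold higher, and PGIP1, which encodes a polygalacturonase-inhibiting protein of the cell wall, was 2.84-fold higher. NADP-ME2, a malic enzyme, was 1.94-fold higher, and PPC3, a phosphoenolpyruvate carboxylase, was 2.00-fold higher. Photosynthesis genes had a median log2 ratio of -0.54, and genes of the abscisic-acid response had a median of -0.25. Of the genes named here, only STOP2 passed over all genes tested. No photosynthesis gene passed over its list alone, and the camera calls of both lists were lost with an estimated correlation. That correlation was 0.70 for photosynthesis genes and -0.03 for abscisic-acid genes. The latter lies below the preset 0.01, so the lost abscisic-acid call is not a sign of correlated members.

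STOP2 was the 1 gene of 25384 past the threshold at low pH (fitted log2 ratio 4.70, SE 0.17, adjusted p = 0.00666 in limma), and it was higher on 3 of 3 arrays. At an unadjusted p under 0.05, 704 genes passed, 384 higher and 320 lower, against 1269.2 expected by chance. The STOP2 probe lies on chromosome 5 at 7653591 to 7653650 in the array annotation, whose genome build the files do not give. STOP1 (AT1G34370) had a fitted log2 ratio of -0.09 (SE 0.10) and did not pass the test, with 0.16 when arrays were centred on their median. That centring also moved the median of all genes at low pH to 0.14. The STOP2 call was lost without low pH replicate 1, low pH replicate 2 or Al replicate 1, each time with 0 genes past the threshold in limma and 497, 504 and 910 genes at an unadjusted p under 0.05.

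Of the 16 measured STOP1-regulated tolerance genes, 5 rose and 0 fell adjusted over the list alone, and 0 passed over all genes tested. CIPK23 rose by 1.33 on the log2 scale (SE 0.15), NADP-ME2 by 0.95 (SE 0.15), PGIP1 by 1.51 (SE 0.40), RAE1 by 0.48 (SE 0.13) and NADP-ME1 by 0.41 (SE 0.12). Without low pH replicate 3, PGIP1 stood at 0.92. RAE1 encodes an F-box protein that targets STOP1 for degradation. The other log2 ratios were 0.60 for the malate channel gene ALMT1, 0.55 for the citrate transporter gene MATE, 0.32 for POP2, 0.25 for ALS3, 0.24 for GDH1, 0.24 for AKT1, 0.14 for SULTR3;5, 0.10 for GDH2, 0.08 for TDT, -0.06 for NRT1.1 and -0.99 (SE 0.38) for the potassium transporter gene HAK5. Those of NRT1.1 and TDT changed sign with another scaling, to 0.18 when arrays were centred on their median and to -0.01 with Feature Extraction processed signals. The list had a median log2 ratio of 0.29 (camera adjusted p = 3.85e-08), with adjusted p = 0.333 with an estimated correlation. PGIP2 is on the array but did not pass the signal filter. Part of this list may have been chosen on the same arrays by the study, so its direction is not independent evidence. The count fell to 2 without low pH replicate 2, Al replicate 1 or Al replicate 2, and the slide 2 arrays alone gave 4 with a median of 0.21.

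In the list of GABA shunt and pH-regulating metabolism, 2 of 20 measured genes rose adjusted over the list alone, PPC3 by 1.00 (SE 0.15) and NADP-ME2, and GAD3, a glutamate decarboxylase gene, fell by 0.41 (SE 0.10). None of the 20 passed over all genes. The list median was 0.06 (camera adjusted p = 0.0535), and without low pH replicate 2 the count past the threshold was 1. In the potassium, proton and calcium transport list only CIPK23 of 15 genes passed over the list alone. In that list the median (6.83e-05), the mean (-0.05) and the direction of the set test (down) differed in sign. In the pathogen-defence list CYP71A13, a camalexin synthesis gene, rose by 1.34 (SE 0.22) and WRKY53 by 0.58 (SE 0.12) over the list alone, while the list median was -0.09 and turned to 0.06 with median centring. Those 2 calls were lost without low pH replicate 1, Al replicate 1 or Al replicate 3, and on slide 2 alone, and 1 remained with median centring.

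Abscisic-acid and dehydration genes were lower at low pH: 12 of 14 measured genes had negative ratios, and NCED3, which encodes the rate-limiting enzyme of abscisic-acid synthesis under drought, fell by 0.62 (SE 0.14) and HAI1 by 0.63 (SE 0.15) over the list alone, with 0 passing over all genes. The list median was -0.25 (camera adjusted p = 2.52e-07), with adjusted p = 0.217 with an estimated correlation. The count was 0 without low pH replicate 1, low pH replicate 2 or Al replicate 2, and 0 on slide 2 alone or with median centring, but 5 without Al replicate 1. The oxidative-stress list had a median of -0.23 (camera adjusted p = 8.01e-06), with adjusted p = 0.333 with an estimated correlation, and its lowest-p members were CSD1 at -0.34 (SE 0.07) and GSTU25 at -0.60 (SE 0.21). Photosynthesis genes, fixed as markers of shoot tissue, had 13 of 14 negative ratios and a median of -0.54 (camera adjusted p = 9.77e-11), with adjusted p = 0.381 with an estimated correlation. PSAD-1 stood at -0.69 (SE 0.16) and LHCB3 at -0.61 (SE 0.18), and none of the 14 passed over the list alone. On the slide 2 arrays with the dye term the median was -0.42 and 7 fell over the list alone, and the count was 8 without Al replicate 1 or Al replicate 3, 6 with slide as a block and 9 with separate fits.

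The other lists called by camera at low pH held no member past the threshold, over the list alone or over all genes. Hypoxia genes had a median of 0.19 (camera adjusted p = 0.00444; adjusted p = 0.531 with an estimated correlation), with HRE2 at 0.29 and HRA1 at 0.19. Meristem and cell-cycle markers had a median of 0.14 (camera adjusted p = 0.00132; adjusted p = 0.485 with an estimated correlation), with CDKB2;1 at 0.30 and KNOLLE at 0.30. Phenylpropanoid genes had a median of 0.15 (camera adjusted p = 0.0233; adjusted p = 0.572 with an estimated correlation), with CCOAOMT1 at 0.30 and C3H1 at 0.45. Iron-deficiency genes had a median of 0.13 (camera adjusted p = 0.0233; adjusted p = 0.622 with an estimated correlation), with CYP82C4 at 1.50 (SE 0.32) and BHLH100 at 0.91 (SE 0.31), but a median of -0.07 on the slide 2 arrays. Nitrogen genes had a median of -0.12, which turned to 0.11 with median centring (camera adjusted p = 0.00251; adjusted p = 0.381 with an estimated correlation), with NIA2 at -0.19, also turned with median centring, to 0.05, and AMT1;5 at -0.27. Root-hair markers had a median of -0.22, which was 0.03 without low pH replicate 3 (camera adjusted p = 0.0127; adjusted p = 0.531 with an estimated correlation), with COBL9 at -0.31 and EXPA7 at -0.25. The hypoxia median was -0.03 without low pH replicate 3.

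The lists not called at low pH, besides those of GABA metabolism, potassium transport and pathogen defence, also held no member past the threshold over the list alone. Their medians were 0.07 for sulphate transport and sulphur starvation (SULTR1;1 at 0.81, SDI2 at 0.37), 0.06 for xylem and phloem (XCP2 at 0.20, XCP1 at 0.17) and -0.10 for the root cap (SMB at -0.18, BRN1 at -0.18). The medians of the following lists turned positive with median centring. They were -0.05 for cell-wall loosening (EXPA1 at -0.31, XTH5 at -0.18), -0.02 for endodermis and suberin (FAR5 at -0.25, CASP5 at -0.06) and -0.07 for flavonoid synthesis (MYB75 at -0.13, UGT78D2 at -0.10). They were -0.05 for heat shock (HSFA2 at 0.35, HSP70 at -0.29), -0.03 for other Al-resistance genes (STAR1 at -0.17, XTH31 at -0.24) and -0.04 for phosphate starvation (LPR2 at 0.32, PHT1;2 at -0.19). Median centring moved the median of all genes at low pH to 0.14. Of these members, UGT78D2, STAR1 and PHT1;2 also turned positive with it. In all, camera called 10 of 22 lists at low pH, 5 up and 5 down, and with an estimated correlation 0 remained, with 3 at an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way on balance, called 0.

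**Figure D1:**
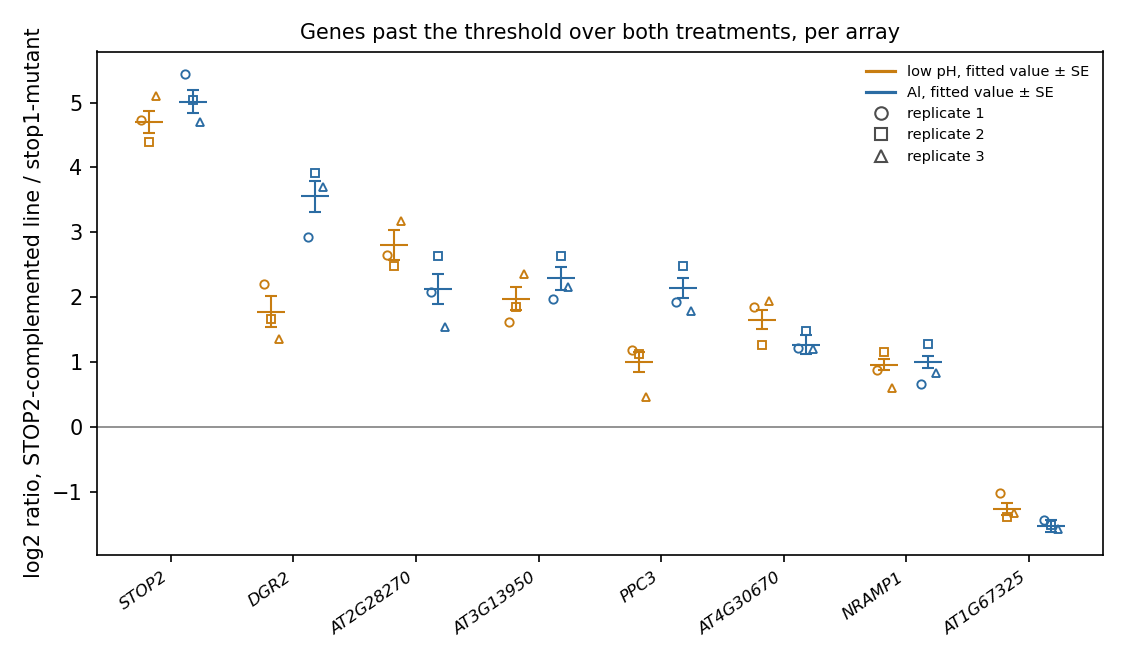
Log2 ratio of the STOP2-complemented line to stop1-mutant for the 8 genes past the threshold over both treatments; horizontal marks with bars are the fitted value ± SE per treatment and open symbols the 3 arrays of each treatment. STOP2 lies between 4.39 and 5.44 on all 6 arrays, and AT1G67325 is the 1 gene below 0.

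In Al, STOP2 was 32.3-fold higher in the STOP2-complemented line, with array log2 ratios averaging 5.06 ± 0.37 (SD, n = 3). Of the STOP1-regulated tolerance genes 13 of 16 rose adjusted over the list alone, 6 without Al replicate 2, and 0 over all genes. Their median log2 ratio was 0.94 (camera adjusted p = 0.112 with an estimated correlation). The 13 included ALMT1 at 2.76-fold (array log2 ratios 0.16, 2.45 and 1.35), MATE at 1.72-fold, PGIP1 at 6.18-fold and the vacuolar malate transporter gene TDT at 2.00-fold. PPC3 was 4.42-fold higher, and the plasma-membrane proton pump gene AHA2 was 1.86-fold higher. Of the photosynthesis genes 10 of 14 fell adjusted over the list alone and 0 over all genes, with a median of -0.84 (camera adjusted p = 0.316 with an estimated correlation).

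STOP2 was again the 1 gene past the threshold over all genes (fitted log2 ratio 5.01, SE 0.17, adjusted p = 0.00459 in limma, higher on 3 of 3 arrays). At an unadjusted p under 0.05, 1166 genes passed, 542 higher and 624 lower, against 1269.2 expected by chance. STOP1 had a fitted log2 ratio of -0.08 (SE 0.10) and did not pass the test. The count was 0 in limma without Al replicate 1 or Al replicate 2, with 1593 and 594 genes at an unadjusted p under 0.05, 2 without low pH replicate 1 and 3 without low pH replicate 3. It was 15 with slide as a block.

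Of the tolerance genes, PGIP1 rose by 2.63 on the log2 scale (SE 0.40), SULTR3;5 by 1.68 (SE 0.37), ALMT1 by 1.46 (SE 0.33), CIPK23 by 1.34 (SE 0.15) and NADP-ME2 by 1.31 (SE 0.15). HAK5 rose by 1.12 (SE 0.38), TDT by 1.00 (SE 0.10), RAE1 by 1.00 (SE 0.13), the nitrate transporter gene NRT1.1 by 0.89 (SE 0.22), MATE by 0.78 (SE 0.23) and GDH1 by 0.61 (SE 0.13). NADP-ME1 rose by 0.39 (SE 0.12) and POP2, the GABA transaminase gene, by 0.34 (SE 0.10). ALS3 at 0.24, GDH2 at 0.19 and AKT1 at -0.03 did not pass, and 0 members passed over all genes. SULTR3;5 was above background on 0 of 3 arrays in stop1-mutant and 2 of 3 in the STOP2-complemented line, so it was at least 2.33-fold higher. ALMT1 was above background in stop1-mutant on 1 of 3 arrays in each treatment, and without Al replicate 2 its log2 ratio was 0.78 and did not pass over the list alone. The set test gave camera adjusted p = 1.13e-23 for the list, with adjusted p = 0.112 with an estimated correlation and fry adjusted p = 0.0403. Because the study may have drawn some of these genes from the same arrays, the direction of the list is not independent evidence. The count was 6 without Al replicate 2, 13 on the slide 2 arrays alone (median 0.93) and 14 with slide as a block.

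**Figure D2:**
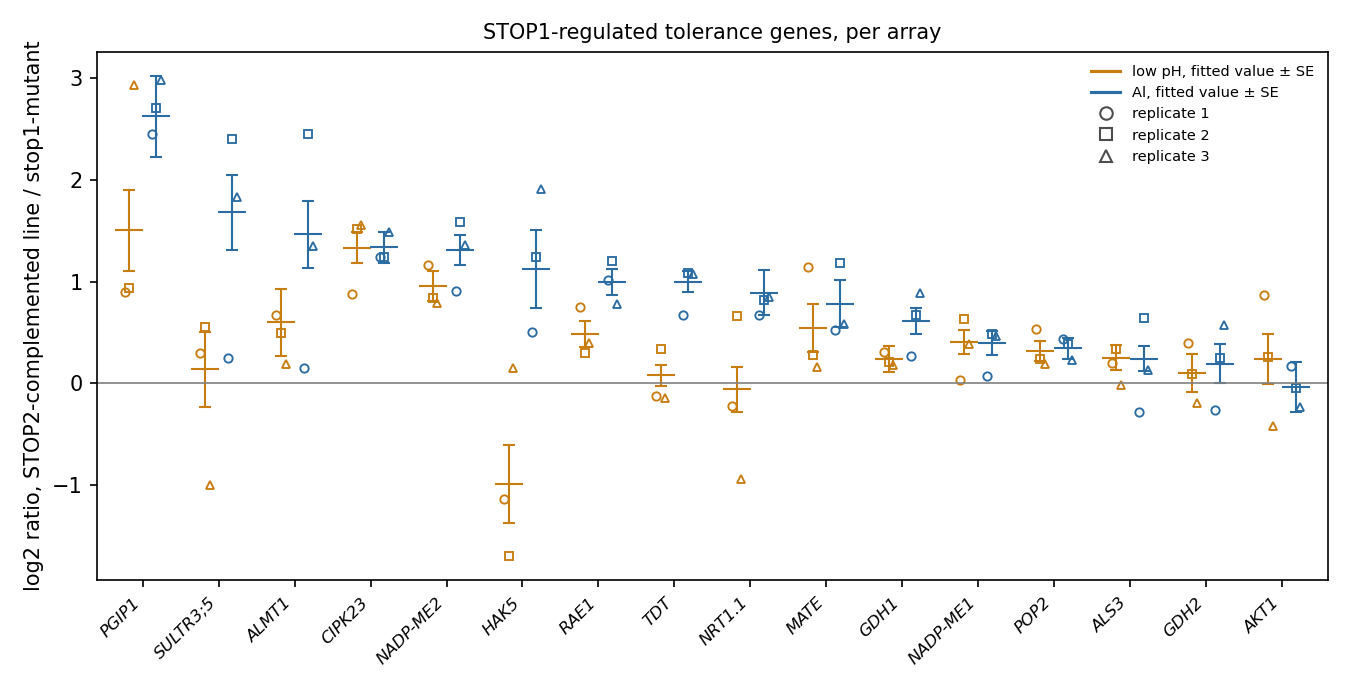
Log2 ratio of the STOP2-complemented line to stop1-mutant for the 16 measured STOP1-regulated tolerance genes at low pH and in Al; horizontal marks with bars are the fitted value ± SE and open symbols the 3 arrays of each treatment. In Al 15 of the 16 fitted values lie above 0, with PGIP1 highest at 2.63, and HAK5 lies at -0.99 at low pH and 1.12 in Al.

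Of 20 measured genes of the GABA shunt and pH-regulating metabolism, 6 rose and 1 fell in Al adjusted over the list alone, and 0 passed over all genes. The list median was 0.10 (camera adjusted p = 1.06e-04), with adjusted p = 0.146 with an estimated correlation. PPC3 rose by 2.15 (SE 0.15), NADP-ME2 as given above, and GAD1, a glutamate decarboxylase gene of roots, by 0.58 (SE 0.10), while GAD3 fell by 0.74 (SE 0.10). GDH1, POP2 and NADP-ME1 were the others that rose, and 4 of the 6 are also in the tolerance list. Without Al replicate 2 the count past the threshold was 2, with median centring 3, and on slide 2 alone it was 5 with a median of 0.02.

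Transport genes moved in both directions. In the potassium, proton and calcium list CIPK23 rose by 1.34, AHA2 by 0.90 (SE 0.15) and KUP6, a potassium transporter gene, by 0.33 (SE 0.08), 3 of 15 over the list alone and 0 over all genes. That list was not called by camera (adjusted p = 0.115) but was by fry (adjusted p = 0.0403, up), and its median (-0.03) and mean (0.17) differed in sign. In the sulphate list SULTR3;5 and SULTR3;1 (1.11, SE 0.26) rose, and SULTR2;1 (-0.89, SE 0.22), a transporter of the vascular tissue, and LSU1 (-0.42, SE 0.08), a marker of sulphur starvation that was above background on 1 of 3 arrays in the STOP2-complemented line, fell over the list alone, with 0 of 18 past the threshold over all genes. The sulphate median was -0.07, its mean 0.03 and its set test pointed down, so these differed in sign, and the median was 0.11 on the slide 2 arrays. In the phosphate list LPR2, a multicopper oxidase gene of the phosphate response, rose by 0.87 (SE 0.10) over the list alone. That was 1 of 21 with a median of 0.10 (camera adjusted p = 0.00652), with adjusted p = 0.417 with an estimated correlation. PHO1;H1 stood at 0.60 (SE 0.27). Without Al replicate 2 SULTR3;1 stood at 0.48, and the counts were 1 for the potassium list, 0 for the sulphate list and 0 for the phosphate list, and the sulphate count was 2 without low pH replicate 1 and 1 without Al replicate 3. With median centring the sulphate count was 2 and the phosphate count 0. GAD1, GAD3, KUP6, SULTR3;1 and SULTR2;1 lie outside the rule for named genes and were chosen after their values were seen.

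Photosynthesis genes fell in Al in 10 of 14 cases over the list alone and 0 over all genes. RBCS3B fell by 1.39 (SE 0.43), LHCB1.1 by 1.24 (SE 0.21), RBCS1A by 1.15 (SE 0.37), PSAD-1 by 1.09 (SE 0.16) and LHCB3 by 1.09 (SE 0.18). LHCA1 fell by 0.86, PSBO1 by 0.83, PSAF by 0.71 and RBCS2B by 0.69, and RBCS1B was the other of the 10. These genes encode Rubisco small subunits and components of both photosystems, and those other than PSAD-1 and LHCB3 were named after their values were seen. The list median was -0.84 (camera adjusted p = 4.17e-15), with adjusted p = 0.316 with an estimated correlation. As a measured fact beside it, 10 markers of shoot epidermis and myrosin cells outside photosynthesis had a median log2 ratio of 0.01 in Al. Most of these markers gave signal well above the floor in these root samples, so this value does not decide whether the amount of shoot tissue differed. By array the photosynthesis median was -0.11, -1.02 and -1.22, RBCS3B stood at -2.03 without Al replicate 1, the count was 0 without Al replicate 2 and 5 without Al replicate 3, and the slide 2 arrays alone gave 12 with a median of -1.12.

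Flavonoid synthesis genes had negative ratios in 10 of 10 cases in Al, and UGT78D2 fell by 0.46 (SE 0.10) and UGT78D1 by 0.36 (SE 0.08) over the list alone. Both encode flavonol glycosyltransferases, and 0 passed over all genes. The median was -0.40 (camera adjusted p = 4.01e-09), with adjusted p = 0.316 with an estimated correlation. The count of 2 became 0 without low pH replicate 2 or Al replicate 2 or with median centring, 1 without Al replicate 3, 9 without Al replicate 1 or with slide as a block, and 10 on the slide 2 arrays (median -0.63). Heat-shock genes had negative ratios in 16 of 17 cases, a median of -0.21 (camera adjusted p = 1.76e-08, adjusted p = 0.112 with an estimated correlation, fry adjusted p = 0.0403) and 0 members past the threshold, with the small heat-shock protein genes HSP17.6A at -0.37 (SE 0.09) and HSP17.4 at -0.32 (SE 0.10). In the endodermis and suberin list PER64 rose by 0.66 (SE 0.11) and ESB1 by 0.61 (SE 0.14) over the list alone, 2 of 15, and both act in the lignification of the Casparian strip. That median was 0.07 (camera adjusted p = 0.00861), with adjusted p = 0.316 with an estimated correlation, and the count was 0 without low pH replicate 2 or Al replicate 2 or with median centring, and 1 without low pH replicate 1. In the cell-wall loosening list XTH4, a xyloglucan endotransglucosylase gene, rose by 1.91 (SE 0.16) over the list alone, while XTH24 stood at 0.97 (SE 0.34) and the median of 20 genes was 0.06 (camera adjusted p = 0.165). Without Al replicate 1 that count was 3, and on slide 2 alone it was 2.

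The remaining lists held no member past the threshold in Al, over the list alone or over all genes, apart from NRT1.1 of the tolerance list, which did not pass over the nitrogen list. Medians called by camera were 0.21 for hypoxia (adjusted p = 6.18e-04; PCO2 at 0.48, HRA1 at 0.24), 0.24 for iron deficiency (adjusted p = 3.33e-04; NAS1 at 0.79, F6'H1 at 0.58) and 0.10 for meristem and cell cycle (adjusted p = 9.49e-04; PLT1 at 0.22, CDKB2;1 at 0.17). They were -0.15 for abscisic acid (adjusted p = 0.00364; RD29B at -0.33, RD29A at -0.58) and -0.17 for oxidative stress (adjusted p = 0.00669; UPOX at -0.21, UGT74E2 at -0.81). With an estimated correlation these calls were lost, with adjusted p = 0.316 for hypoxia, meristem and oxidative stress, adjusted p = 0.536 for iron, whose median was 0.00 on slide 2, and adjusted p = 0.238 for abscisic acid. Lists not called had medians of 0.00 for nitrogen, which was -0.02 with median centring (NIA2 at 0.38), -0.05 for other Al-resistance genes (CAMTA2 at 0.22, XTH17 at 0.19), -0.04 for pathogen defence (VSP2 at -0.74, CYP71A13 at 0.77), 0.04 for the root cap (BRN2 at 0.37, FEZ at -0.07), -0.13 for root hairs (EXPA7 at -0.35, COBL9 at -0.37) and -0.11 for xylem and phloem (IRX9 at -0.21, CESA8 at -0.22). The phenylpropanoid median was 0.02, its mean -0.02 and its set test pointed down, and the median was -0.02 with median centring and -0.11 on slide 2 (4CL3 at -0.46, F5H1 at -0.22). In all, camera called 12 of 22 lists in Al, 7 up and 5 down. With an estimated correlation 0 were called, with 4 at an unadjusted p under 0.05, and fry called 3, the tolerance, potassium and heat-shock lists. The heat-shock list went from an unadjusted camera p = 3.19e-09 to 0.00780, although its estimated correlation of -0.006 lay below the preset 0.01. Its lost call is therefore not a sign of correlated members. The same holds for the abscisic-acid list (-0.03) and the GABA list (0.001). By contrast, the estimated correlation was 0.79 for flavonoid, 0.70 for photosynthesis and 0.65 for iron-deficiency genes.

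**Figure D3:**
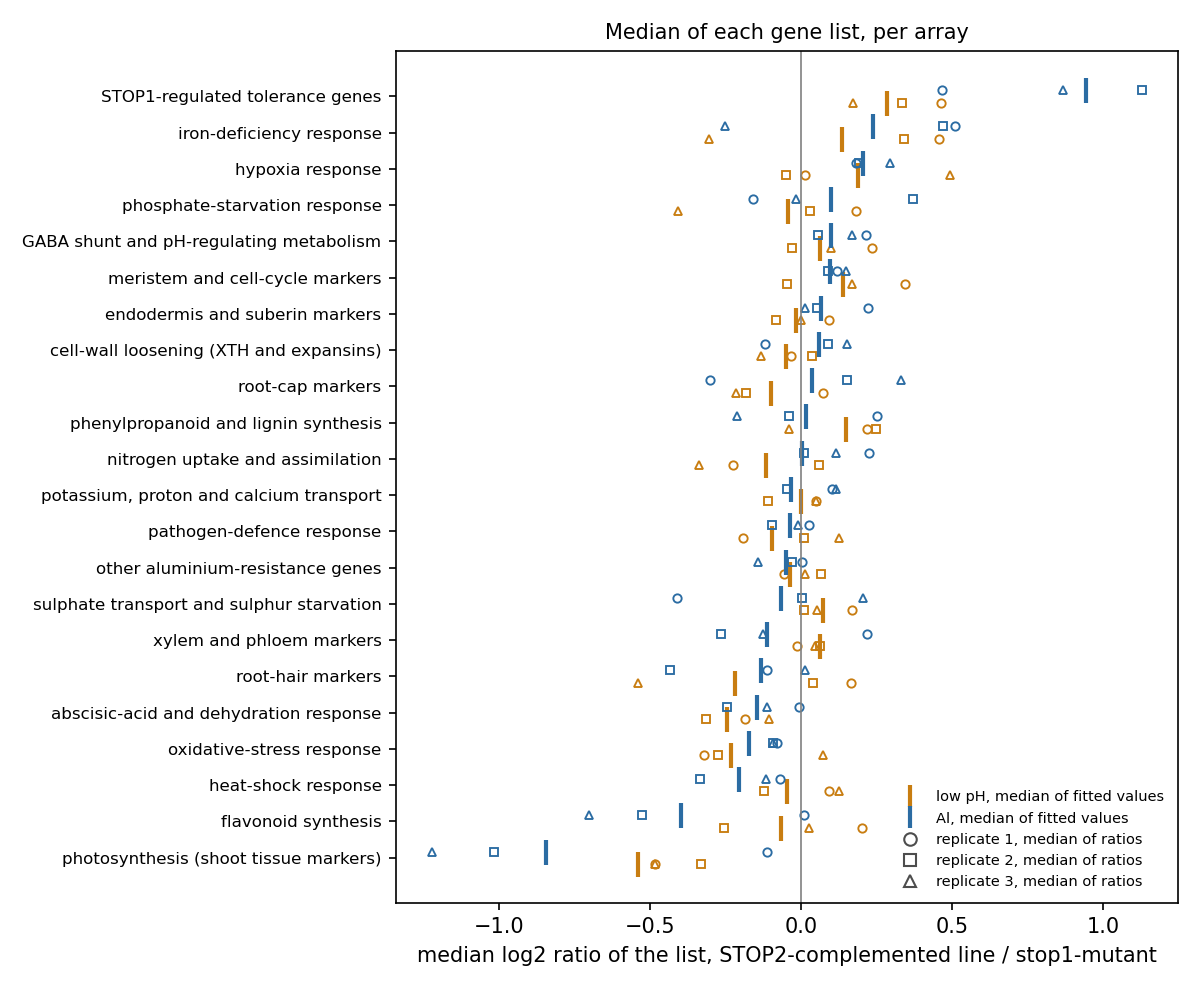
Median log2 ratio of the STOP2-complemented line to stop1-mutant over the measured members of each of the 22 gene lists, at low pH and in Al; vertical marks are medians of fitted values and open symbols the medians of the 3 arrays of each treatment. The STOP1-regulated tolerance genes lie highest in Al at 0.94 and the photosynthesis genes lowest at -0.84.

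The line difference was compared directly between Al and low pH. PPC3 had a line difference larger in Al by 1.14 on the log2 scale (SE 0.21), TDT by 0.92 (SE 0.14) and XTH4 by 1.70 (SE 0.22), each past the threshold over its own list alone. Tolerance genes shifted by a median of 0.36 between the treatments (camera adjusted p = 1.75e-08), and photosynthesis genes by -0.34 (camera adjusted p = 0.00184), and on the slide 2 arrays alone by 0.65 and -0.71. These set tests had adjusted p = 0.314 or higher with an estimated correlation. By array the tolerance medians were 0.47, 0.34 and 0.17 at low pH and 0.47, 1.13 and 0.87 in Al (replicates 1 to 3). Al replicate 1 was thus level with low pH replicate 1, and the tolerance shift came from Al replicates 2 and 3, both on slide 2. The size of the photosynthesis shift also depended on single arrays. Without Al replicate 3 the photosynthesis medians at low pH and in Al were -0.57 and -0.65. They were -0.49 and -0.65 without Al replicate 2, and -0.48 and -1.12 without Al replicate 1. Over all genes 0 passed in limma, and 348 did at an unadjusted p under 0.05, against 1269.2 expected by chance. Camera called 10 of 22 lists for the difference, 6 up and 4 down, 0 remained with an estimated correlation, with 2 at an unadjusted p under 0.05, and fry called 0. The meristem list (median -0.02, mean -0.02, test up), the other Al-resistance list (median -0.01, mean 0.01, test up) and the root-hair list (median -0.03, mean 0.10, test up) differed in sign between these measures.

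Across the 25384 genes, the fitted line differences of the 2 treatments correlated with Pearson's r = 0.48 and Spearman's rho = 0.25. Genes are not independent replicates, and the shared dye term adds a covariance of 0.00145 to an observed 0.0131. At an unadjusted p under 0.05, 166 genes were higher in both treatments against 8.20 expected if independent, 143 were lower in both against 7.87, and 3 went opposite ways. The 2 tests share each gene's variance estimate, so they are not independent and the expected counts are only a rough guide. Of all genes, 56.5% had the same sign in both treatments. Of the genes past the adjusted threshold, STOP2 was shared. Within slide 2 the correlation was 0.33, and leaving out 1 array gave 0.30 to 0.46.

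Over both treatments together, 8 genes passed the threshold, 7 higher and 1 lower in the STOP2-complemented line, each with the same sign on 6 of 6 arrays. DGR2 (AT5G25460), a cell-wall protein gene of the DUF642 family, was 6.34-fold higher, AT2G28270, a DC1-domain protein gene, 5.51-fold, and AT3G13950, of unknown function, 4.39-fold. PPC3 (AT3G14940) was 2.97-fold higher, AT4G30670, of unknown function, 2.75-fold, and NRAMP1 (AT1G80830), the root manganese and iron transporter gene, 1.97-fold. AT1G67325, which encodes a Ran-binding zinc-finger protein, was 2.64-fold lower.

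In limma the adjusted p was 8.80e-04 for STOP2 (fitted log2 ratio 4.86, SE 0.13) and 0.0147 for AT1G67325 (-1.40, SE 0.07). It was 0.0358 for NRAMP1 (0.98, SE 0.06), AT3G13950 (2.13, SE 0.13) and DGR2 (2.66, SE 0.17), and 0.0360 for AT2G28270 (2.46, SE 0.17), PPC3 (1.57, SE 0.11) and AT4G30670 (1.46, SE 0.10). At an unadjusted p under 0.05, 1429 genes passed, 696 higher and 733 lower, against 1269.2 expected by chance. By treatment, DGR2 stood at 1.78 at low pH and 3.55 in Al, AT2G28270 at 2.80 and 2.12, and AT4G30670 at 1.65 and 1.26. The AT1G67325 probe lies on chromosome 1 at 25213770 to 25213829, and that of NRAMP1 on chromosome 1 at 30377963 to 30378022. Those of AT3G13950 and PPC3 lie on chromosome 3 at 4604466 to 4604525 and 5029414 to 5029473. The DGR2 probe lies on chromosome 5 at 8865276 to 8865335, that of AT2G28270 on chromosome 2 at 12061408 to 12061467 and that of AT4G30670 on chromosome 4 at 14957442 to 14957501. The count fell to 4 without low pH replicate 1 or 3 and to 1 without any 1 of the other 4 arrays, and it was 31 with slide as a block and 0 with the slide 2 arrays and the dye term.

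At a looser adjusted p under 0.1, 29 genes passed over both treatments and 13 in Al, and the names that follow were chosen after their values were seen. Over both treatments CIPK23 stood at 1.34 (adjusted p = 0.0543 in limma) and NADP-ME2 at 1.13 (adjusted p = 0.0685). TMT1, a vacuolar sugar transporter gene, stood at 0.94 (adjusted p = 0.0528), and the leucine-rich repeat kinase genes AT1G51830 and AT1G51850 at 2.63 and 1.44 (both adjusted p = 0.0543). In Al alone DGR2 stood at 3.55 (adjusted p = 0.0606), PPC3 at 2.15 (adjusted p = 0.0694), XTH4 at 1.91 and ABCG40, an abscisic-acid importer gene, at -0.99 (both adjusted p = 0.0844).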

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

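The tests of a dye effect, of a slide effect and of an array in the wrong treatment, and the comparison of treatments within each line, were chosen only after the result was seen.

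The median log2 ratio of photosynthesis genes was -0.54 at low pH and -0.84 in Al, a shift of -0.34 between the treatments (camera adjusted p = 0.00184, and adjusted p = 0.510 with an estimated correlation). With an estimated correlation the 2 lists themselves had camera adjusted p = 0.381 and 0.316, and at low pH no member passed over the list alone. Al replicate 1 had a list median of -0.11, above that of each low pH array. Without Al replicate 3 the medians at low pH and in Al were -0.57 and -0.65. A dye effect is argued against: the list median was negative on both dye-swapped arrays, the higher at -0.33, and on the other 4. Unequal amounts of shoot tissue stay open, although 10 markers of shoot epidermis and myrosin cells had a median log2 ratio of 0.014 in Al (95% bootstrap interval -0.07 to 0.16), which met the condition set beforehand for excluding this. That condition was judged wrong after the values were seen. The 10 markers passed the signal filter in these root samples, at a median log2 intensity of 10.7 (LTPG1 highest at 13.1) beside 9.01 for the photosynthesis genes. Whether that signal came from root cells or from shoot tissue was not tested. Levels of different probes compare only roughly, but signal from root cells could hide a small share of shoot RNA. Of the 10, TGG2 at 7.14, MYB60 at 7.60 and CER1 at 7.89 lie near the floor, with log2 ratios of 0.014, 0.006 and -0.15 in Al. A difference in time of day at harvest also stays open, with 6 morning minus 6 evening clock genes at -0.37 in Al (interval -0.96 to 0.08) and -0.29 at low pH (interval -0.99 to -0.18). Over both treatments the morning genes CCA1 and LHY, named after their values were seen, stood at -0.81 (SE 0.18) and -0.80 (SE 0.12). RVE8 and LNK1 stood at -0.27 and -0.06, and PRR9 and PRR7 at 0.12 and 0.05. The evening genes lay between 0.11 and 0.26. A difference between the lines themselves was not tested.

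Arrays of one treatment disagreed across the genome, with correlations of log2 ratios over genes of -0.34 between low pH replicates 2 and 3 and -0.12 between Al replicates 1 and 3. A dye effect as the whole cause is argued against, since orientation explained 27.6% of the first component (38.9% of the variance). For low pH replicates 2 and 3 a slide effect is argued against, since the -0.34 was found within slide 2. Low pH replicate 3 and Al replicate 1, on different slides, correlated at 0.41. That pair shares a dye orientation, whereas low pH replicates 2 and 3 do not, so setting 0.41 beside -0.34 mixes slide with dye. A first test of an array in the wrong treatment decides nothing: the lowest correlation of mean log2 intensity within a treatment (0.970, low pH replicates 1 and 2, on different slides) differed by -0.00278 from the highest between treatments (0.972, low pH replicate 3 and Al replicate 2, on the same slide), but these pairs have no array in common and mix slide with treatment. An array in the wrong treatment is argued against by 2 tests chosen after the first: over 500 genes and on a scale of 0 for low pH and 1 for Al, low pH replicate 3 stood at 0.119 and Al replicate 1 at 1.01, a difference of 0.895, and with each array placed by the other 5 the low pH arrays stood at -0.06 to 0.13 and the Al arrays at 0.92 to 1.00, a gap of 0.797. For Al a slide effect stays open, as replicates 2 and 3 on slide 2 correlated at 0.38, which is 0.333 above the higher of their correlations with replicate 1 on its own slide (0.04 and -0.12), the labels do not say whether the replicate 1 arrays came from separate experiments, and no biological explanation was tested.

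AT1G67325 was lower on all 6 arrays, with a fitted log2 ratio of -1.40 over both treatments. A change that spans neighbouring genes is argued against, since the 10 nearest measured genes had a median log2 ratio of -0.019 (95% bootstrap interval -0.09 to 0.03). A dye effect is argued against too, as the higher of the 2 dye-swapped arrays stood at -1.40 and the other 4 lay between -1.58 and -1.03. What stays open, and was not tested, is whether the change follows STOP2 itself or a difference between the lines at this locus alone.

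The line difference differed between Al and low pH in camera for 9 more lists, by the median shifts that follow, each with adjusted p = 0.314 or higher with an estimated correlation. Tolerance genes shifted by 0.36 (adjusted p = 1.75e-08), although Al replicate 1 had a list median of 0.47, level with low pH replicate 1. Nitrogen genes shifted by 0.34 (adjusted p = 1.79e-04). Phosphate-starvation genes shifted by 0.14 (adjusted p = 0.00270). Cell-wall loosening genes shifted by 0.13 (adjusted p = 0.00258). Endodermis and suberin markers shifted by 0.12 (adjusted p = 0.00128). Genes of the GABA shunt and pH-regulating metabolism shifted by 0.10 (adjusted p = 0.0124). Flavonoid genes shifted by -0.37 (adjusted p = 3.58e-06). Heat-shock genes shifted by -0.26 (adjusted p = 8.88e-05). Phenylpropanoid genes shifted by -0.14 (adjusted p = 0.0282).

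Over their own list alone the line differences of PPC3 (1.14), TDT (0.92) and XTH4 (1.70) were larger in Al. UPOX went opposite ways on every array of the treatments, with array means of 0.09 at low pH and -0.22 in Al, and the difference itself had an adjusted p = 1.00 in limma.

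Other splits of the arrays were fitted in the same way. Over both treatments 1 of 30 fitted sign splits gave as many genes, the real one with 8 against at most 5 in the others. That share is under 0.05, but it concerns the count as a whole, which includes STOP2. Chance is not excluded for single genes among the 8, and the count was 1 to 4 with an array left out. The split that gave 5 reversed the ratios of low pH replicate 3 and Al replicate 1, the arrays that correlated at 0.41. What its count reflects was not tested. Of the 32 splits 2 could not be fitted with the dye term, 1 of them the split that follows the dye. Without the dye term the real split gave 51 genes, the others at most 2 and the one that follows the dye 0. The 4 sign splits of low pH and the 4 of Al are too few for a share under 0.05, with 1 of 4 splits giving as many genes in each, the real one with 1 against 0 in the others. The 10 splits for the difference are also too few, with 10 of 10 giving as many, the real one 0 and the highest other 45. That other split set low pH replicates 1 and 2 with Al replicate 2 against the rest. It puts both arrays with the STOP2-complemented line in Cy5 on one side, and what its count reflects was not tested.

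Single-channel intensities, which the comparisons of the report do not use, gave 1756 genes that differed between Al and low pH in stop1-mutant and 1333 in the STOP2-complemented line. The 10 splits of the 6 arrays are too few for a share under 0.05, with 1 of 10 giving as many genes in each line, the real one against at most 0 in the others.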

How the results depend on the processing

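All alternatives were fixed before the data were examined, except the slide 2 settings, which were chosen after seeing the data. For each of them that moved a result the cause was not tested, save that fewer arrays were used where arrays were left out. The numbers of genes past the threshold for low pH, Al and both treatments and the numbers of lists called changed with the setting, whereas the correlation of the treatments stayed positive in every setting.

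For low pH, 1 gene became 2 with normexp offset 16, 2 with median centring, 7 with no dye term, 0 with the replicate block in place of the dye term, 0 with trend and robust eBayes, and 0 with and 2 without the dye term on slide 2, and leaving out 1 array gave 0 to 1 (0 without low pH replicate 1, low pH replicate 2 or Al replicate 1). For Al, 1 gene became 3 with offset 16, 2 with no dim-probe filter, 21 with no dye term, 0 with the replicate block, 15 with slide as a random block, 6 with separate fits, 0 with trend and robust eBayes, and 0 with and 9 without the dye term on slide 2, and leaving out 1 array gave 0 to 3 (0 without Al replicate 1 or 2). Over both treatments, 8 genes became 5 with Feature Extraction processed signals, 13 with offset 16, 5 with the series table, 51 with no dye term, 1 with the replicate block, 31 with slide as a random block, 0 with trend and robust eBayes, and 0 with and 19 without the dye term on slide 2. Leaving out 1 array gave 1 to 4. Of the 8 genes, 4 remained with processed signals and with the series table, 5 of the 9 genes called with median centring were among them, 7 remained with the strict dim-probe filter, 8 with offset 16, with no dye term and with slide as a block, 1 with the replicate block, 4 on slide 2 without the dye term, and 1 to 3 with an array left out. The count for the difference was 0 in limma in every setting, with 106 to 1321 genes at an unadjusted p under 0.05. Where a setting gave 0 genes in limma for low pH, Al or both, 497 to 2069 had an unadjusted p under 0.05, against 1269.2 expected by chance.

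Replicate numbers do not pair the arrays: deviations from the treatment mean correlated at -0.12, 0.29 and -0.27 for numbers 1, 2 and 3, so the replicate block served as an alternative only, and it replaced the dye term because replicate 2 is the dye-swapped array.

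Camera called 10 lists at low pH, but 0 with an estimated correlation and 0 with fry, and 7 to 12 with an array left out. In Al it called 12, but 0 with an estimated correlation and 3 with fry, and 8 to 14 with an array left out. The 5 tolerance genes past the threshold over the list alone at low pH became 3 with processed signals, with the series table and with trend and robust eBayes, and 2 to 4 with an array left out. The 13 in Al became 6 to 13 with an array left out. A called list median changed sign for nitrogen at low pH (0.11 with median centring), for iron at low pH (-0.073 in both slide 2 settings, and -0.073 to 0.40 with an array left out) and, with an array left out, for hypoxia (-0.034 to 0.25) and root hairs (-0.50 to 0.030) at low pH. Median centring put the median of all genes at low pH at 0.14, so the nitrogen median still lay below it. An alternative called the opposite sign for xylem and phloem markers at low pH (-0.12 to 0.087 with an array left out) and for phenylpropanoids in Al (-0.11 in both slide 2 settings, and -0.11 to 0.12 with an array left out). The correlation of the line differences, 0.48, became 0.42 with processed signals, 0.39 with median centring, 0.42 with the series table and 0.33 in both slide 2 settings, and 0.30 to 0.46 with an array left out.

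A sign change counts as a reversal where either value was called, and otherwise as a move. Of the list medians, 573 kept their direction and side of the threshold, 28 gained and 16 lost the threshold, 38 moved and 5 reversed, and with arrays left out these were 214, 14, 12, 19 and 5. Of the values of 123 named genes, 3435 kept both, 135 gained and 123 lost the threshold and 86 moved, and with arrays left out these were 1288, 38, 140 and 58, with 0 reversals. A minimum of 2-fold left 7 of the 8 genes over both treatments, without NRAMP1, and the other counts as they were. The separate fits give no value for the difference. Signal over background limits SULTR3;5 and ALMT1, which were above background in stop1-mutant on 0 and 1 of 3 arrays in Al, and LSU1, above background in the STOP2-complemented line on 1 of 3 arrays in Al.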

Other observations

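The comparison of Al with low pH within each line was added after seeing the data, and its genes were chosen by their values, while the test of nuclear transport genes was set before the values of its 17 genes were looked at.

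Roots in Al differed strongly from roots at low pH in both lines, in pH as well as in Al and partly in slide. Iron-deficiency genes were much lower in Al: 18 of 22 fell adjusted over the list alone in stop1-mutant and 18 of 22 in the STOP2-complemented line, with median log2 ratios of -2.69 and -2.92 (-2.66 and -2.71 on slide 2). The ferric reductase gene FRO2 fell, with log2 ratios of -5.06 in stop1-mutant and -4.67 in the STOP2-complemented line, as did the regulator genes BHLH100 (-3.69 and -3.95) and MYB72 (-4.10 and -4.12). Of other metal genes, which were not tested as a list, ZIP3 (-5.31 and -4.33), COPT2 (-4.25 and -3.81) and MTPA1 (-5.94 and -5.40) fell. AT1G29100, annotated as a copper-binding family protein gene, rose (5.76 and 5.94). HAK5 fell (-7.28 and -5.17), and of 15 nitrogen genes 12 and 11 fell and 2 and 2 rose over the list alone.

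Higher in Al were the E3 ligase gene PUB54, by 6.01 and 5.77, the stress transcription factor gene NAC019, by 4.30 and 4.22, the dehydration protein gene LEA4-5, by 4.01 and 3.77, and EDS16, the isochorismate synthase gene of salicylic-acid synthesis, by 4.09 and 3.97. The flavonoid genes CHI (2.17 and 1.68) and CHS (1.66 and 1.45) and the cell-wall gene XTH24 (2.70 and 3.27) were also higher. In limma 1756 of 25342 genes passed in stop1-mutant, 896 higher and 860 lower in Al, and 1333 in the STOP2-complemented line, 662 higher and 671 lower. Of these 1231 were shared, all in the same direction, but the lines were hybridised to the same arrays (intraspot correlation 0.777), so the overlap is not independent evidence. On slide 2 alone, which holds 4 of the 6 arrays, 660 and 550 genes passed, of which 530 and 399 were among the 1756 and 1333. For the mean of both lines on slide 2, PUB54, EDS16, MTPA1, FRO2 and AT1G29100 did not pass (adjusted p = 0.0701 to 0.274 in limma). NAC019, LEA4-5, BHLH100, MYB72, ZIP3, COPT2 and HAK5 did pass there.

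The importin genes IMPA-1 (-0.65, adjusted p = 0.0877 in limma) and IMPA-2 (-0.61, adjusted p = 0.0575) and the Ran-binding protein 1a gene AT1G07140 (-0.84, adjusted p = 0.0627) were near the threshold and lower over both treatments. A hypothesis that genes of nuclear import and export are lower as a group was tested on 17 others, whose median log2 ratio was 0.0080 (95% bootstrap interval -0.03 to 0.04), with 7 of 17 negative. That argues against a lower level of the group as a whole, and a change confined to these 3 genes may still be real.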
